A study of Mus musculus with 6 samples.

How the data were processed

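RNA from whole mouse embryos at embryonic day 8.5 was measured on 6 single-colour Affymetrix arrays, 3 from Fzd7 single knockout embryos and 3 from Fzd2 Fzd7 double knockout embryos. Per the labels' protocols, total RNA was extracted with Trizol and RNeasy and labelled with biotin by the standard protocol of the array maker. Groups and replicate numbers were taken from the sample titles. The labels do not say whether a sample was 1 embryo or a pool, nor whether replicates came from separate litters, so the p-values measure the spread between these samples, which may be partly technical.

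The authors deposited 1 table of log2 values for 45101 probe sets, made with RMA (robust multi-array average) per the submitters' processing notes. RMA corrects background, scales the arrays to a common distribution and summarises the probes of each probe set on the log2 scale. The scale was taken from the values themselves, which ran from 2.64 to 15.17 with array medians between 5.794 and 5.816. The RMA version, the probe definitions and the scanner software are not given in the sources used here, and raw scans were not used here. Because RMA compresses differences near background, dim genes have understated fold changes. The number of arrays limits the precision of every value.

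Probe sets were named through the platform's annotation table. Of the 45101 probe sets, 64 were controls, 34945 had a single gene symbol, 932 had several and 9160 had none listed. Probe sets with several symbols or none were left out of the gene-level test. Gene identifiers were checked against a RefSeq gene table of the GRCm38.p6 assembly, used for names only. Identifiers of 99.12% of the genes matched and 0 symbols needed an update. Each of the 18193 genes was represented by its probe set with the highest mean over the 6 arrays, a choice that mattered for 9010 genes with several probe sets.

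The double knockout was compared with the single knockout in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05. Fzd2 and Fzd7 were reported first, because genotype at Fzd2 is what separates the groups. For these genes an exact two-sided permutation test of 3 against 3 values was added, whose smallest possible p is 0.1.

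Genes were named by a fixed rule: Fzd2 and Fzd7, then up to 12 genes per direction past the threshold with non-overlapping groups. Where fewer than 5 passed in a direction, genes were filled up to 8 by smallest unadjusted p. From each gene list came its members past the threshold (at most 5), or else the 2 with the smallest unadjusted p. Predicted and cDNA-clone genes were not named. Other genes are named in places, with a statement that they were picked after their values were seen.

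Gene lists numbering 33 covered Wnt signalling, planar cell polarity, embryonic tissues, Hox genes, other signalling pathways, stress and cell cycle genes, adjacent extraembryonic and maternal tissue, sex-linked genes and the chromosomal neighbours of Fzd2. Of their 503 members, 464 were measured, and Fzd2 was left out of every list test. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. The same test with a correlation estimated per list, and fry, were run beside it. The estimated correlation allows for genes of a list that vary together between samples of a group. Counts "adjusted over the list alone" treat the members of a list as the only genes tested.

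The comparison, its tests, the gene lists and the rule for named genes were fixed before the data were examined. So were these alternatives: the replicate number as a block, an intensity trend with robust moderation, leaving out genes below the median brightness, testing all probe sets, averaging the probe sets of a gene, a second quantile normalization, median centring, array weights, an adjusted p threshold of 0.1, an added 1.5-fold requirement, a covariate for Y-linked expression and leaving out each array in turn. Combinations with the first double knockout array left out were added after that array was seen to stand apart.

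The scripts were tested on simulated data drawn with the spread of the real genes. With all 6 arrays the gene test recovered 86% of genes changed by 2-fold and 95.6% of those changed by 4-fold, and 5.47% of its calls were false. The list test gave p under 0.05 for 6.36% of unshifted lists and called the cell cycle list, shifted by 0.5 on the log2 scale, in 100% of 20 simulated tables. These simulated genes varied independently, which favours the tests over real gene lists. Each simulated table held 50 changed genes per fold size, which eases the adjusted threshold. The recovered shares therefore do not apply to a gene that changes alone. A 1.5-fold change was simulated as well, but its recovered share is not given here. The shares above do not cover changes under 2-fold.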

Results

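Gene expression was compared between whole mouse embryos that lacked Fzd7 and embryos that lacked both Fzd2 and Fzd7, at embryonic day 8.5. Fzd2 and Fzd7 (written Fz2 and Fz7 in the labels) encode closely related Frizzled proteins, cell surface receptors for Wnt ligands. At this stage the embryo forms somites, closes its neural tube, loops its heart tube and fills its yolk sac with primitive red cells. Each group had 3 arrays, called single knockout and double knockout replicates 1 to 3. All were of a mixed genetic background, and wild-type embryos or embryos lacking Fzd2 alone were not analysed here. The question was what loss of Fzd2 adds to loss of Fzd7.

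Fzd2 mRNA was strongly reduced in all 3 double knockout arrays. The brightest of its 3 probe sets read 9.86, 9.99 and 10.01 in single knockout replicates 1 to 3, and 7.30, 7.69 and 7.63 in the double knockout. Fzd2 fell by 2.42 on the log2 scale (SE 0.11, n = 3 per group, limma adjusted p = 0.00567), to 18.7% of the single knockout level. The exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. The remaining Fzd2 probe sets lay lower by a similar amount, with log2 differences of -2.73 and -2.33, though neither passed when all probe sets were tested, at limma adjusted p = 0.0561 and 0.527. The call was lost with the mean of the probe sets (adjusted p = 0.0691), with a covariate for Y-linked expression (0.0720) and without any 1 of single knockout replicates 1 to 3 or double knockout replicate 3 (0.0831, 0.120, 0.109 and 0.0759), with differences of -2.49 to -2.39. Fzd7, deleted in both groups, read 4.92 ± 0.01 and 4.89 ± 0.10 (SD, n = 3) on its brighter probe set. The position of these probe sets relative to the deleted parts is not given in the sources used here, so the Fzd7 values do not check the labels. The Fzd2 values separate the groups as labelled.

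**Figure D1:**
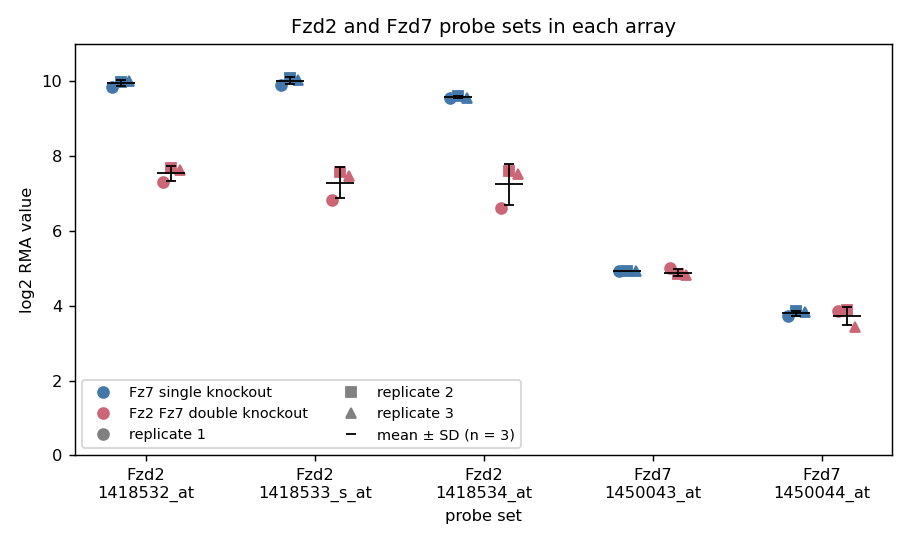
Log2 RMA values of the 3 Fzd2 and 2 Fzd7 probe sets in each array, with the mean and SD of the 3 arrays per group. All double knockout arrays lie between 6.62 and 7.69 for Fzd2, below the single knockout arrays at 9.55 or above, while the Fzd7 values of both groups overlap.

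Beyond Fzd2 no gene passed the threshold. Of 18193 genes, 1 was lower and 0 were higher in the double knockout by limma, and the second smallest adjusted p was 0.872. At an unadjusted p under 0.05 there were 902 genes, 356 higher and 546 lower, against 910 expected by chance. Groups did not overlap for 2083 genes, or 11.4%, where chance gives 10%. The named genes other than Fzd2 are therefore given as values that did not pass the test.

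The genes with the smallest unadjusted p after Fzd2 did not pass the threshold in either direction. On the lower side Cxcl12, a chemokine that guides migrating cells, differed by -0.77 (SE 0.10). Hoxa5, a Hox gene of the neck and upper trunk, differed by -0.69 (SE 0.10), and Fgf9, a fibroblast growth factor, by -0.40 (SE 0.06). Sostdc1, a secreted inhibitor of BMP and Wnt signalling, had the largest difference of these genes after Fzd2 at -1.36 (SE 0.24). Nrarp, a target and feedback inhibitor of Notch, differed by -0.42 (SE 0.08). The endothelial gene Esm1 and the neuronal membrane protein gene Slitrk6 differed by -0.67 and -0.78. On the higher side the values were 0.61 for the platelet-derived growth factor gene Pdgfd, 0.64 for Frmpd2, 0.61 for the synaptic organiser Cbln1, 0.42 for Fam210b, 0.34 for Rabgap1l, 0.30 for Unc13c, 0.28 for Slc35d3 and 0.29 for Isl1, a transcription factor of cardiac progenitors and motor neurons. All of these genes had groups that did not overlap, and each had an adjusted p of 0.872. Esm1, Slitrk6, Frmpd2, Unc13c and Slc35d3 were dim, with group means from 3.63 to 5.12, below the array medians.

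Double knockout replicate 1 stood apart from the other 5 arrays. It correlated with them at 0.987 to 0.990 across genes, whereas the others correlated with each other at 0.997 to 0.998. In it 479 genes lay more than 1 log2 unit from the mean of the other 5 arrays, 211 higher and 268 lower, against 18 to 37 genes in any other array. The embryonic globins of primitive red cells were lower in it. Hbb-y read 4.05 against a mean of 12.4 in the other 5 arrays, and Hbb-bh1 and Hba-x differed by -6.67 and -6.60. The ventricular myosin light chain gene Myl2 differed by -3.92 and the neural gene Zic1 by -4.01. On the higher side stood the pluripotency factors Pou5f1 (4.42) and Nanog (3.15), the streak-stage ligand gene Wnt8a (3.36), the yolk sac lipoprotein gene Apob (3.84) and the placental genes Cts7 (3.71), Prl7a1 (3.67) and Prl5a1 (3.44). These genes were picked after their values were seen. Some of these differences were not confined to this array. Without it the groups still differed by -1.39 for Zic1, -0.55 for Myl2, 1.09 for Pou5f1 and 0.87 for Wnt8a. Fzd2 in this array was 7.30, the lowest of the 6. Of 63 genes whose group means differed by over 1 log2 unit, 23 differed by under 0.5 without this array. Without it limma again called 1 gene, Fzd2, and 1213 genes had an unadjusted p under 0.05. For each list called either with or without this array, both results are given.

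Of the 33 gene lists, 12 were called by camera at the preset correlation, 5 higher and 7 lower in the double knockout. No list was called with an estimated correlation, where the smallest adjusted p was 0.556, or by fry, where it was 0.492. Without double knockout replicate 1 there were 10 calls, 3 higher and 7 lower, of which 7 matched a call with all arrays in direction. Then fry called 1 list, the Hox genes of paralog groups 5 to 9, and the estimated correlation 0. Apart from Fzd2 no list member passed over all genes, and 12 members of 7 lists passed when adjusted over the list alone.

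Hox genes of the trunk were lower as a group in each double knockout array. Hox genes give cells their position along the head-to-tail axis, and those of paralog groups 5 to 9 mark the levels from the neck to the posterior trunk. Of 13 measured, 9 were lower, with a median of -0.47, and list means were -0.83, -0.32 and -0.25 in double knockout replicates 1 to 3. Hoxa5, Hoxc9 and Hoxc5 passed when adjusted over the list alone (adjusted p = 0.00324, 0.0308 and 0.0437) and 0 passed over all genes. Hoxc9 differed by -0.71 (SE 0.17), and Hoxc5, named after its value was seen, by -0.84 (SE 0.23). Hoxb5, Hoxb6 and Hoxb7, also named after their values were seen, differed by 0.01, 0.13 and 0.01. The list was called lower by camera (adjusted p = 3.15e-05; adjusted p = 0.556 with an estimated correlation). Without double knockout replicate 1 the median was -0.26, with adjusted p = 2.52e-08 by camera, 0.0427 by fry and 0.285 with an estimated correlation.

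The more anterior Hox genes of paralog groups 1 to 4, which pattern the hindbrain and neck, were lower for 8 of 10 members, with a median of -0.32. Hoxa3 (-0.27, SE 0.07) and Hoxb4 (-0.22, SE 0.06) passed when adjusted over the list alone, both at adjusted p = 0.0333, and 0 passed over all genes. Camera called this list lower (adjusted p = 0.00228; adjusted p = 0.556 with an estimated correlation). Without double knockout replicate 1 its median was -0.17 and it stayed called (adjusted p = 0.00314; adjusted p = 0.814 with an estimated correlation). Hox genes of paralog groups 10 to 13, which act in the tail and limbs, were split 5 to 5 with a median of -0.0023, a mean of 0.020 and an adjusted p of 0.953. Their median changed sign between scalings of the arrays. Hoxc10 and Hoxc13 differed by -0.36 and -0.22 (-0.21 and -0.28 without double knockout replicate 1), and 0 members passed when adjusted over the list alone.

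Genes of the epiblast, the pluripotent tissue that precedes gastrulation, were higher. Of 15 genes 13 were higher, with a median of 0.23, and list means were 0.98, 0.19 and 0.31 in double knockout replicates 1 to 3. Pou5f1, which encodes the pluripotency factor Oct4, read 10.77, 6.69 and 7.32 in these arrays against 6.51, 5.31 and 5.92 in the single knockout, a difference of 2.35 (SE 1.04). Dppa4 differed by 0.23 (SE 0.06). With all 6 arrays no member passed over all genes or when adjusted over the list alone. The list was called higher (adjusted p = 1.41e-05; adjusted p = 0.556 with an estimated correlation). Without double knockout replicate 1 the median was 0.19 and the list stayed called (adjusted p = 4.02e-07; adjusted p = 0.288 with an estimated correlation). Pou5f1 then differed by 1.09 and did not pass when adjusted over the list alone. The 1 member that did pass was Tdgf1 (0.70), named after its value was seen. In double knockout replicate 1 itself Tdgf1 lay on the other side of the single knockout, at -0.79.

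**Figure D2:**
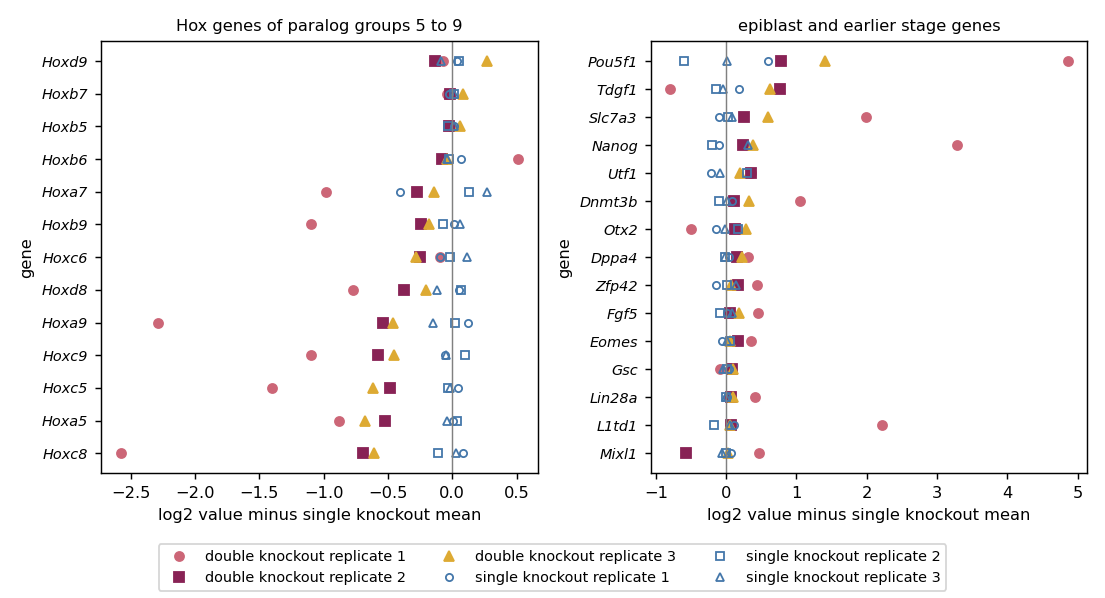
Log2 value of each Hox gene of paralog groups 5 to 9 and each epiblast gene in the 6 arrays, minus the mean of the single knockout arrays. Hoxa5 lies at -0.88, -0.52 and -0.68 in the double knockout arrays, and Pou5f1 at 4.86, 0.78 and 1.40.

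Mesoderm lists differed in direction and in their dependence on replicate 1. Somite and paraxial mesoderm genes were lower for 14 of 15 members, with a median of -0.21. Meox1, a somite transcription factor, differed by -0.58 (SE 0.15), and the muscle determination gene Myf5 by -1.25 (SE 0.44). Without double knockout replicate 1 these differences were -0.45 and -0.79. No member passed over all genes or when adjusted over the list alone, and the list was called lower (adjusted p = 0.000709; adjusted p = 0.645 with an estimated correlation). It stayed called without double knockout replicate 1 (median -0.061, adjusted p = 0.0161; adjusted p = 0.817 with an estimated correlation) but not with dim genes left out (adjusted p = 0.0506). Primitive streak and presomitic mesoderm genes were lower for 13 of 21 members and were not called (adjusted p = 0.822), with a median of -0.021 but a mean of 0.040. Fgf17 and the Notch ligand gene Dll1 differed by -0.34 and -0.14, or -0.36 and -0.23 without double knockout replicate 1. List means of the streak genes were 0.39, -0.20 and -0.07 in double knockout replicates 1 to 3, and without replicate 1 the list was called lower (median -0.066, adjusted p = 0.00703; adjusted p = 0.814 with an estimated correlation). The allantois and extraembryonic mesoderm list was higher for 7 of 11 members and not called (median 0.12, adjusted p = 0.323). Postn, which encodes the matrix protein periostin, differed by -0.95 (SE 0.22) and was the only member to pass when adjusted over the list alone (adjusted p = 0.0481), and Spin2c differed by 0.49.

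Blood, heart and vessel genes were lowest in individual double knockout arrays. Primitive erythroid genes were lower for 14 of 15 members, with a median of -0.68. Klf1, the master regulator of red cell genes, differed by -1.20 (SE 0.52) and Ermap, a red cell membrane protein gene, by -0.68 (SE 0.29). Hbb-y, examined after its values were seen, read 4.05, 13.51 and 9.28 in double knockout replicates 1 to 3 against 12.85 to 13.53 in the single knockout. List means were -2.41, 0.18 and -1.51, so double knockout replicate 2 did not share the lower level. The list was called lower (adjusted p = 3.15e-05; adjusted p = 0.625 with an estimated correlation), also without replicate 1 (median -0.53, adjusted p = 0.0041; adjusted p = 0.817 with an estimated correlation), where only replicate 3 lay lower, and 0 members passed over all genes or when adjusted over the list alone. Cardiac genes were lower for 18 of 24 members without a call (median -0.44, adjusted p = 0.298). The natriuretic peptide gene Nppa differed by -1.70 (SE 0.89), or -0.69 without double knockout replicate 1, and Isl1, at 0.29 (SE 0.06), was the only member to pass when adjusted over the list alone (adjusted p = 0.0488). The cardiac list means were -1.36, 0.10 and -0.02, and without replicate 1 the list was called higher (median 0.070, adjusted p = 0.0151; adjusted p = 0.814 with an estimated correlation), whereas it was called lower without double knockout replicate 2 or 3 (adjusted p = 0.0085 and 0.0447; with all arrays, adjusted p = 0.900 with an estimated correlation). Endothelial genes were lower for 16 of 18 members and called lower (median -0.22, adjusted p = 0.0318; adjusted p = 0.873 with an estimated correlation). Lyve1, a hyaluronan receptor, differed by -0.72 and the vessel wall gene Plvap by -0.79 (-0.59 and -0.21 without double knockout replicate 1), with 0 members past the threshold adjusted over the list alone. Without replicate 1 the endothelial median was 0.073 and the call was lost (adjusted p = 0.300), as it was without single knockout replicate 1 or 2 (adjusted p = 0.251 and 0.0996).

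Neural lists had medians below 0 and were lowest in double knockout replicate 1. Neural plate and early brain genes were lower for 15 of 25 members and not called (median -0.062, adjusted p = 0.412). En2, a midbrain and hindbrain gene, differed by -1.44 (SE 0.34) and the neurogenic factor Neurog2 by -1.17 (SE 0.30). Without replicate 1 the neural median was 0.021, on the other side of 0, with no call (adjusted p = 0.341), while without double knockout replicate 3 the list was called lower (adjusted p = 0.0258; with all arrays, adjusted p = 0.900 with an estimated correlation). Neural crest genes were lower for 11 of 16 members and called lower (median -0.31, adjusted p = 0.0317; adjusted p = 0.836 with an estimated correlation). Ednrb, the endothelin receptor of crest cells, differed by -0.64 (SE 0.24) and Erbb3 by -0.32 (SE 0.12), or -0.35 and -0.20 without double knockout replicate 1. The crest call was lost without replicate 1 (median -0.061, adjusted p = 0.300), and without single knockout replicate 1 or 2 (adjusted p = 0.0992 and 0.0686). With all 6 arrays no member of either neural list passed over all genes or when adjusted over the list alone. Without replicate 1, 5 neural plate members passed when adjusted over the list alone, and none over all genes. En2 (-1.19), Neurog2 (-0.88), Zic1 (-1.39) and Olig2 (-0.91) were lower and Egr2 (0.76) was higher. The last 3 were named after their values were seen. No crest member passed in that setting.

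Endoderm, node and midline lists had medians above 0. All 19 visceral endoderm genes, which serve nutrient transport in the yolk sac, were higher, with a median of 0.82, and the list was called (adjusted p = 3.15e-05; adjusted p = 0.836 with an estimated correlation). Their list means were 2.52, -0.06 and -0.03, and without double knockout replicate 1 the median was -0.065 with no call (adjusted p = 0.738). The apolipoprotein gene Apoa2 and the fibrinogen gene Fgb differed by 0.81 and 0.73, and by 0.17 and 0.21 without this array. Gut endoderm genes were higher for 13 of 17 members and called higher (median 0.18, adjusted p = 0.0197; adjusted p = 0.556 with an estimated correlation). Sox17, an endoderm determinant, differed by 0.47 (SE 0.18) and Foxa1 by 0.26 (SE 0.10), or 0.27 and 0.24 without double knockout replicate 1. The gut call was lost without that array (median 0.059, adjusted p = 0.330) or without single knockout replicate 2 (adjusted p = 0.110). Node and left-right genes were higher for 7 of 7 members (median 0.16, adjusted p = 0.00674; adjusted p = 0.625 with an estimated correlation), among them the Nodal co-receptor gene Cfc1 (1.00, SE 0.41) and Nodal itself (0.35, SE 0.15). That call was also lost without replicate 1 (adjusted p = 0.310), with a median of -0.00014 and a mean of 0.30. Lefty2, named after its values were seen, weighed on this mean, at 0.56 and 2.43 in double knockout replicates 2 and 3. Without replicate 1, 3 members were higher and 4 lower. Cfc1 and Nodal then differed by 0.57 and 0.20. Notochord and axial midline genes were higher for 7 of 9 members and not called (median 0.083, adjusted p = 0.0709), with 0.27 for the BMP inhibitor Nog, but were called with the mean of all probe sets (median 0.083, adjusted p = 0.0309) and without single knockout replicate 3 or double knockout replicate 3 (adjusted p = 0.0217 and 0.0456; in the main comparison, adjusted p = 0.556 with an estimated correlation). No member of these 4 lists passed over all genes or when adjusted over the list alone.

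Markers of trophoblast and of maternal decidua and leukocytes, tissues next to the embryo, were not called. The trophoblast list had a median of 0.032 and a mean of 0.042 over 8 genes while camera pointed lower (adjusted p = 0.828), and Elf5 and Psg17 differed by -0.38 and -0.16. The maternal list had a median of -0.045 and a mean of 0.033 over 17 genes, with camera pointing higher (adjusted p = 0.873), and Cd52 and Nkg7 differed by 0.13 and 0.17 (0.09 and 0.06 without double knockout replicate 1). No member of either list passed when adjusted over the list alone.

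Wnt pathway lists were not called in the main comparison of all 6 arrays, which weights the arrays alike and keeps dim genes. The other Frizzled receptors and Wnt co-receptors, 15 genes, were split 7 higher to 8 lower (median -0.0046, adjusted p = 0.695), a median whose sign changed between scalings, and none passed when adjusted over the list alone. Wnt ligand genes were lower for 13 of 19 members (median -0.034, adjusted p = 0.351), and were called only with dim genes left out (adjusted p = 0.00335), with no call for the full list with an estimated correlation (adjusted p = 0.836). Wnt6 (-0.41, SE 0.08) and Wnt5b (-0.39, SE 0.08) both passed when adjusted over the list alone (adjusted p = 0.0204) and not over all genes. Without double knockout replicate 1, Wnt8a, which was higher (0.87), passed over the list alone as well (limma adjusted p = 0.0411). Among 18 secreted Wnt modulators the median was 0.0047 and the mean -0.094 (adjusted p = 0.828), and Sostdc1 and the Wnt inhibitor gene Dkk2 (-0.60, SE 0.13) passed when adjusted over the list alone (adjusted p = 0.0203 and 0.0291). Without double knockout replicate 1, Cer1 (-0.43), named after its value was seen, passed over the list alone as well (limma adjusted p = 0.0457). In replicate 1 itself Cer1 lay 0.69 above the single knockout. Beta-catenin dependent Wnt targets were lower for 13 of 20 members (median -0.040, adjusted p = 0.127), with -0.31 (SE 0.07) for the cyclin gene Ccnd1 and -0.28 (SE 0.07) for the feedback inhibitor Nkd2, and 0 passed when adjusted over the list alone. Their list means were 0.20, -0.23 and -0.05 in double knockout replicates 1 to 3, and without replicate 1 this list was called lower (median -0.18, adjusted p = 9.96e-05; adjusted p = 0.814 with an estimated correlation), as it was with all 6 arrays under array weights (median -0.14, adjusted p = 0.00333) and without single knockout replicate 2 (adjusted p = 0.00477; in the main comparison, adjusted p = 0.836 with an estimated correlation). Planar cell polarity genes, which orient cells within a sheet, were lower for 13 of 21 members and not called (median -0.046, adjusted p = 0.822), with 0.27 for Celsr3 and -0.37 for Dchs1 (-0.15 without double knockout replicate 1), and 0 passed when adjusted over the list alone. When double knockout replicate 1 was left out they were higher for 13 and lower for 8, with a median of 0.0042 and no call (adjusted p = 0.924).

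Of the other signalling lists, Notch and BMP were called. Notch pathway genes were lower for 12 of 16 members (median -0.11, adjusted p = 0.0129; adjusted p = 0.625 with an estimated correlation) and stayed called without double knockout replicate 1 (median -0.040, adjusted p = 0.0236; adjusted p = 0.814 with an estimated correlation) but not without single knockout replicate 1 (adjusted p = 0.0992). Nrarp passed when adjusted over the list alone (adjusted p = 0.0203), and the receptor gene Notch1 differed by -0.24 (SE 0.07) without passing. BMP target genes were higher for 10 of 12 members (median 0.13, adjusted p = 0.00745; adjusted p = 0.556 with an estimated correlation), also without replicate 1 (median 0.12, adjusted p = 0.00993; adjusted p = 0.814 with an estimated correlation) but not without double knockout replicate 3 (adjusted p = 0.0527). Msx2, a BMP-induced transcription factor, differed by 0.24 (SE 0.10) and the inhibitor Smad7 by 0.19 (SE 0.08), or 0.14 and 0.14 without double knockout replicate 1. Of the BMP targets, 0 passed when adjusted over the list alone. Hedgehog targets (median -0.035 over 7 genes, adjusted p = 0.742), FGF targets (median 0.035 over 12 genes, adjusted p = 0.966) and retinoic acid genes (median -0.062 over 11 genes, adjusted p = 0.630) were not called. Their named members were Gli1 (-0.12) and Foxa2 (0.17), Il17rd (-0.23) and Spry1 (-0.29), and Crabp2 (-0.55) and Hoxb1 (0.26). Without double knockout replicate 1 these values were -0.10 and 0.06, -0.15 and -0.19, and -0.32 and 0.09. None passed when adjusted over the list alone.

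Stress and proliferation lists were near 0. Medians were -0.0044 for 14 p53 targets (adjusted p = 0.811, with a mean of 0.012 and a median whose sign changed between scalings), -0.081 for 15 hypoxia and glycolysis genes (adjusted p = 0.157, or 0.0418 without double knockout replicate 3; with all arrays, adjusted p = 0.836 with an estimated correlation) and 0.0048 for 14 cell cycle genes (adjusted p = 0.630). Trp53inp1 and Pmaip1, both p53 targets, differed by 0.25 (SE 0.06) and 0.65 (SE 0.30), or 0.25 and 0.30 without double knockout replicate 1, the hypoxia genes Hk2 and P4ha1 by -0.14 and -0.19 (-0.09 and -0.06 without that array), and the mitotic genes Bub1 and Cdc20 by 0.09 and 0.09. The 36 measured neighbours of Fzd2 on chromosome 11 had a median of -0.015 while camera pointed higher (adjusted p = 0.978), with Lsm12 at 0.17 and Meox1, also a member of the somite list, at -0.58. No member of these 4 lists passed over all genes or when adjusted over the list alone.

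Sex-linked genes split the arrays within both groups. Xist, expressed from the inactive X chromosome of females, read 12.71 in single knockout replicate 2 and 12.46 and 12.77 in double knockout replicates 1 and 3, and between 5.58 and 5.84 in the other arrays. The Y-linked gene Uty read 3.41 to 3.68 in those 3 arrays and 8.22 to 8.45 in the other 3. Each array thus showed either high Xist or high Y-linked expression and not both, although the labels describe the samples as of mixed gender. The group differences were 2.31 (SE 2.56) for Xist and -1.63 (SE 1.78) for Uty, or 1.26 and -0.77 without double knockout replicate 1, and the 4 measured sex-linked genes were not called (adjusted p = 0.795) and 0 passed when adjusted over the list alone.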

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

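Combined settings without double knockout replicate 1 were chosen after the data were seen, and the others before. The count of 1 gene, Fzd2, held with the replicate block, trend and robust moderation, dim genes left out, all probe sets, a second quantile normalization, median centring, array weights, the looser threshold and the added fold requirement. It was 0 with the mean of all probe sets and with the Y-linked covariate. With each array left out it ranged from 0 to 1, at 0 without each single knockout array or double knockout replicate 3. Fzd2 kept its call without double knockout replicate 1 or 2. Without double knockout replicate 1 it was 2 with trend and robust moderation (Fzd2 and Hoxc8) and 3 with all probe sets, all of Fzd2. Fzd2 was lower under all 17 alternatives, by log2 values from -2.73 to -2.30, and passed under 9, with limma adjusted p from 0.000363 to 0.527. It missed the threshold on its other probe sets (-2.727 and -2.332), with the mean of probe sets (-2.492), with the Y-linked covariate (-2.389) and without those 4 arrays, within -2.492 to -2.297 over the arrays left out. The 12 list calls became 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and no double knockout replicate 1, and 1 with fry and no such array. Lists whose camera direction in a setting differed from the main comparison, with a call in at least 1 of that pair, were the cardiac, endothelial and visceral endoderm lists. Their medians without double knockout replicate 1 were 0.0699, 0.0730 and -0.0654, with the Y-linked covariate as well 0.0639, 0.0608 and -0.0402, and with array weights 0.00964 for endothelial genes. Over each array left out, these medians ranged from -0.773 to 0.0699, -0.402 to 0.0730 and -0.0654 to 1.27. The direction of the neural plate list also varied. Camera called it lower without double knockout replicate 3 (adjusted p = 0.0258) and pointed higher, with no call, without double knockout replicate 1 (adjusted p = 0.341). Calls of lists were also lost with dim genes left out (somite, crest, endothelial), with array weights (crest, endothelial, gut, node, visceral endoderm) and with the Y-linked covariate (crest, endothelial). With all 6 arrays kept, lists newly called at the preset correlation were beta-catenin targets with array weights, Wnt ligands with dim genes left out and notochord genes with the mean of all probe sets, and leaving out single arrays gave further calls and losses. The cause of these changes was not tested. The 74 named genes besides Fzd2 kept their sign and stayed short of the threshold under each alternative run on them. The replicate block gave -2.418 for Fzd2 (limma adjusted p = 0.0234) and 12 lists. Deviations of same-numbered arrays from their group means correlated at 0.0941, -0.0368 and -0.130. Double knockout replicate 1 pulls the mean of its group, so these correlations cannot exclude shared litters or batches. The numbers were not taken as pairs, because no pairing is stated. Dim genes have little signal over background, so small differences in them may be understated or missed here.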

Other observations

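The tests of added tissue and of a proportional copy in replicates 2 and 3, and the genes named without double knockout replicate 1, were chosen only after the results they bear on were seen.

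Without double knockout replicate 1 no gene but Fzd2 passed the threshold (smallest other limma adjusted p = 0.475). Of genes outside the named set with small unadjusted p, Fgf18, a fibroblast growth factor gene, differed by -0.74 and Fgfbp3, which encodes a protein that binds such factors, by -0.92. Vwf, the von Willebrand factor gene of vessel walls, differed by -0.70, and 3 genes of the HoxC cluster, Hoxc4, Hoxc5 and Hoxc8, by -0.45, -0.55 and -0.65. On the higher side stood Egr2, a hindbrain segment gene, at 0.76 and Tdgf1, a Nodal co-receptor gene of the epiblast, at 0.70. In replicate 1 itself Egr2 and Tdgf1 lay on the other side of the single knockout, at -0.37 and -0.79. Among the 10092 probe sets outside the gene-level test 0 passed (limma, smallest adjusted p = 0.751), and 467 had an unadjusted p under 0.05.

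Double knockout replicate 1 stood apart through low globin, cardiac and somite genes and high epiblast and visceral endoderm genes. Extraembryonic or maternal tissue added to this sample would lower all embryonic lists alike, but its streak list mean exceeded its cardiac list mean by 1.75 on the log2 scale, which argues against added tissue as the source of the lower genes. For the higher genes added tissue cannot be told apart from an earlier stage, since visceral endoderm genes exceeded epiblast genes by 1.53 and a younger embryo may also carry more visceral endoderm per cell, while the placental genes Cts7, Prl7a1, Prl5a1 and Cts8 (3.71, 3.67, 3.44 and 2.96 above the other 5 arrays) and the decidual gene Prl8a2 (2.41 above the single knockout), all picked after they were seen, go with added tissue, and the fixed trophoblast and maternal lists had means of 0.09 and 0.28. An earlier stage of this sample is a candidate explanation. Later-stage minus earlier-stage genes outside the fixed lists differed by -0.66 at the median. The 11 earlier genes lay at percentile 100 and the 15 later genes at percentile 0.03 of 10000 random lists of like brightness. Those lists drew genes singly, so genes of a set that vary together reach such percentiles more easily. The percentiles also rest on 1 array. These control genes showed no sign of poor RNA, as the 3′ minus 5′ control signal lay below the highest other array for Gapdh (-0.0279) and Actb (-0.0281). For Actb the gap was less than the SD of those arrays (0.0544), so poor RNA is not excluded. Whether an earlier stage would come from genotype or from collection was not tested.

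List means of trunk Hox genes were lower and those of epiblast genes higher in all 3 double knockout arrays, which may reflect lost Fzd2 or a technical difference between the groups. Sex composition is argued against, because the Hox median with the Y-linked covariate was -0.446 and kept 95.6% of its size. A proportional smaller copy of the replicate 1 shift is argued against for the cardiac list, the only list tested in this way. Its mean in replicates 2 and 3 lay 0.51 above the value that copy predicts (SE over genes 0.051). Cardiac genes varied together (estimated correlation 0.531), so this SE is too small. It also leaves out the spread between embryos and the error of the Hox ratio used for the prediction. A shared delay of another form stays open: over disjoint arrays and across genes, which are not independent replicates, the shift of replicate 1 correlated with that of replicates 2 and 3 at 0.0856 to 0.168, from -0.028 to -0.014 with replicate 2 alone and from 0.147 to 0.277 with replicate 3 alone, and in replicates 2 and 3 the earlier genes had a median of 0.034 (percentile 93.0) while the later genes, which a delay would lower, had one of 0.014 (percentile 74.1). A smaller difference in age between litters would also lower Hox genes and raise epiblast genes, and cannot be told apart from an effect of genotype here.

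The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. As many genes as the real split's 1 came from 2 of the 10 splits, and the highest other split, which parts the arrays by sex, gave 4. As many lists as the real 12 came from 1 split, the real one, and the others gave 4 to 11. List calls at the preset correlation thus also arose in splits that mix the genotypes.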
